A study of Mus musculus with 4 samples.

How the data were processed

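Small RNA of exosomes shed into culture medium by 2 mouse colon carcinoma lines, C26 and MC38, was sequenced in 4 libraries. Per the labels, exosomes of each line were isolated once with ExoQuick-TC, a precipitation reagent, and once with a Wako exosome capture ELISA kit, so that each combination of line and kit had 1 library. Below, libraries are named by line and kit. The labels do not say whether the 4 libraries came from separate cultures, and p-values then measure only the spread between these libraries, which can be technical.

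The deposited table holds 1 normalized signal value for each of 795 known mature miRNAs in each library. The submitters' processing notes name DESeq2, without a version. The aligner, counter, genome build and miRBase release are not given in the sources used here. In each column, 100.0% of the nonzero values were whole multiples of 1 step, within a tolerance of 0.006 in the value, and each step was the worth of 1 read in a library with a whole-number total, taken here as the library total. The values were therefore read as RPM, reads relative to that total, and whole reads were recovered from them. The columns sum to between 1020209 and 1057545, as reads that match several mature miRNAs are listed under each of them. For miR-199a-3p and miR-199b-3p, all 4 values are identical, so their reads cannot be divided between them.

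The library totals were 1356801 reads for C26 ExoQuick, 33692 for C26 Wako, 340643 for MC38 ExoQuick and 3867 for MC38 Wako. A single read was thus worth 0.737, 29.7, 2.94 and 259 RPM in that order, and a count of 0 allows up to 2.21, 89.0, 8.81 and 776 RPM, set at 3 counts per library. Exact 95% intervals (Clopper-Pearson for shares and levels, and exact intervals for ratios of reads) were computed from the recovered reads. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries was a duplicate: chi-square per degree of freedom of their reads was at least 17.8.

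Before the data were examined, the tests, the rule for naming miRNAs, the alternatives and 25 miRNA lists were fixed. The main test was limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(value + 1), for the 390 miRNAs with a mean of at least 10 RPM over the 4 libraries. Line and kit entered as additive terms. The fit has 1 residual degree of freedom per miRNA, which is the discrepancy of the line difference between the kits, and the prior degrees of freedom were estimated as infinite, so the spread was in effect taken from the trend over all miRNAs. P-values are two-sided, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Fold changes on the log2(value + 1) scale depend on the pseudocount where a library has 0 reads, and can overstate the change of low miRNAs. For miR-211-3p, 1 read in MC38 Wako against 0 in C26 Wako gave a log2 of −8.02. Differences within 1 kit or 1 line rest on 2 libraries and have no replicate check.

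The 12 largest fold changes per direction among miRNAs past the threshold with the same sign under both kits were named for the line comparison, and 6 per direction with the same sign in both lines for the kit comparison. Where fewer passed, the places were filled by the largest of the smaller within-kit or within-line differences among miRNAs with a mean of at least 100, which are stated not to have passed. The 10 miRNAs with the highest mean over the libraries and members of the fixed lists were also named. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The estimated correlation rests on 1 residual degree of freedom. Its lowest adjusted p over 20 lists was 0.948 for the lines and 0.997 for the kits, so not passing there says little about a list. Camera compares a list with the other miRNAs, so its direction can differ in sign from the median of the list. A list of 2 miRNAs, miR-195a-5p and miR-125b-1-3p, was recalled from a paper on these exosomes, which chose them on these samples.

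Alternatives fixed in advance were other pseudocounts (0.5 and 10), other filters, 4 other scalings, fits without the second factor, leaving out each library in turn, fits without a trend or with robust variances, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. Chosen after seeing the data were a mean of at least 1000, counting identical profiles once, a pseudocount of 1 read of the shallowest library, edgeR with its own expression filter, limma-voom, and the 4 other scalings for the agreement of the kits.

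The fits were tested on simulated data for the line comparison with 390 miRNAs, 200 of them changed, over 20 simulations at a dispersion of 0.3 and the real depths. Of miRNAs with a mean of at least 1000, 20.4% of those changed by a log2 of 2 and 62.2% of those changed by a log2 of 4 were called, against 1.58% of unchanged ones. Below that mean the shares were 1.70% and 8.97%, against 0% of unchanged ones, and the mean estimates were 2.29 and 4.42, above the simulated changes. Camera found the changed list in 20 of 20 simulations and an unchanged one in 1. That changed list held only miRNAs with a mean of at least 1000, drawn independently. All simulated changes were equal under both kits. Lists of low miRNAs, shared reads and discrepancies between the kits were thus not covered.

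Hairpin positions were taken from GENCODE release M21 (GRCm38) by miRNA name, through the RefSeq gene table for symbols, and 787 of the 795 miRNAs had a hairpin gene. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for intervals and plots.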

Results

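Exosomal miRNAs of 2 mouse colon carcinoma lines were compared: C26, whose tumours are widely used to induce wasting (cachexia) in mice, and MC38. Each line gave 1 library of exosomes isolated with ExoQuick-TC and 1 of exosomes bound with a Wako capture kit. Values are RPM, reads relative to a library total. The totals ranged from 3867 reads (MC38 Wako) over 33692 (C26 Wako) and 340643 (MC38 ExoQuick) to 1356801 (C26 ExoQuick), a span of 351-fold. Of 795 mature miRNAs, 687 had reads in C26 ExoQuick, 407 in C26 Wako, 475 in MC38 ExoQuick and 188 in MC38 Wako. When each library was thinned to 3953 listed reads, 147, 216, 134 and 188 were expected in the same order.

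miR-130a-3p led the mean over the libraries and made up 49.0% of MC38 ExoQuick (exact 95% interval 48.8 to 49.1), 17.8% of C26 ExoQuick (17.8 to 17.9), 14.8% of MC38 Wako (13.7 to 15.9) and 6.24% of C26 Wako (5.98 to 6.502). It did not pass the kit test (log2 −1.62 for Wako against ExoQuick, SE 1.02, adjusted p = 0.536). miR-25-3p, of the miR-106b~25 cluster in Mcm7, was second, with 17.6%, 6.77%, 9.22% and 10.3% of C26 ExoQuick, C26 Wako, MC38 ExoQuick and MC38 Wako. let-7b-5p, let-7c-5p, miR-23a-3p, miR-130b-3p, miR-214-3p, miR-24-3p, let-7a-5p and miR-93-5p completed the 10 highest. Together these 10 took 57.9%, 43.7%, 73.4% and 60.9% of the listed reads in that order.

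The main comparison, named by the title of the series, asks which exosomal miRNAs differ between C26 and MC38. In the fit over both kits, exosomes of C26 carried more miR-214-3p, miR-199a-5p, miR-199a/b-3p, miR-221-3p, miR-222-3p, miR-125a-5p, miR-125b-5p and miR-296-3p. Those of MC38 carried more miR-146a-5p and miR-378a-3p. For miR-214-3p and the miR-199 entries, the log2 difference under Wako was only 0.47 to 0.995. For these miRNAs, reads of C26 ExoQuick in the MC38 Wako library could not be told apart from RNA of MC38 exosomes, as described below. In limma with kit as a second term, 13 of 390 miRNAs passed, 11 higher in C26 and 2 higher in MC38, and 11 of the 13 had the same sign under both kits. At unadjusted p under 0.05 there were 46. The median log2 difference over all 390 was 1.85, with 0.29 under ExoQuick and 1.18 under Wako. Only 188 miRNAs had reads in MC38 Wako, and for the rest the difference depends on the pseudocount. With quantile normalization the median was −0.05, so it does not show that C26 exosomes carried more of most miRNAs.

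miR-214-3p and miR-199a/b-3p, typical of fibroblasts and other mesenchymal cells, showed the largest levels among the miRNAs higher in C26. Their relatives miR-214-5p and miR-199b-5p did not pass in limma (adjusted p = 0.442 and 0.369). miR-214-3p stood at 68331 RPM in C26 ExoQuick and 443 in MC38 ExoQuick, a ratio of 154 (exact 95% interval 131 to 182), but at 31165 and 22498 in the Wako libraries, a ratio of 1.39 (1.11 to 1.74). Its fitted log2 difference was 3.87 (SE 0.83, adjusted p = 0.000779). miR-199a-5p differed by a log2 of 4.62 (SE 1.02, adjusted p = 0.000779), and miR-199a-3p and miR-199b-3p, which share all their reads, by 3.23 (SE 0.83, adjusted p = 0.00523). The miR-199a-5p ratio was 328.5 under ExoQuick (128 to 1210) and 1.99 under Wako (0.984 to 4.71, which holds 1). For miR-199a-3p the ratios were 56.5 (50.4 to 63.5) and 1.57 (1.2 to 2.09). The SEs, taken from the trend, leave out these gaps between the kits. Over the alternatives, the log2 ran from 0.95 to 8.29 for miR-199a-5p and from 1.18 to 5.29 for miR-199a-3p. Mir214 (chromosome 1, 162223368 to 162223477, plus strand, GRCm38) and Mir199a-2 (chromosome 1, 162217814 to 162217923, plus strand) lie in an exon of the noncoding RNA Dnm3os, antisense to Dnm3. A second hairpin, Mir199a-1 (chromosome 9, 21496495 to 21496564, minus strand), gives the same mature miR-199a. Of the 9 miRNAs in the list of fibroblast and smooth muscle miRNAs, 4 were called higher in C26 and 5 were not called. Adjusted over the list alone, 6 were higher. The list as a set did not pass (camera adjusted p = 0.678, and adjusted p = 0.948 with an estimated correlation), while miR-143-3p, not called, stood at 9542 and 919 RPM in C26 and MC38 ExoQuick.

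miR-221-3p and miR-222-3p, which repress the cell-cycle inhibitor Cdkn1b, lie next to each other on the X chromosome (Mir221, 19146294 to 19146388, and Mir222, 19146893 to 19146971, minus strand, in no annotated gene of that strand). miR-222-3p differed by a log2 of 3.64 (SE 1.05, adjusted p = 0.0215) and miR-221-3p by 2.68 (SE 0.83, adjusted p = 0.0385). The miR-222-3p ratio was 37.4 under ExoQuick (23.3 to 64.4) and 4.21 under Wako (1.4 to 20.7). For miR-221-3p the ratios were 18.97 (16.7 to 21.6) and 2.18 (1.42 to 3.52). Over the alternatives, the log2 ran from 1.67 to 5.60 for miR-222-3p and from 1.21 to 4.16 for miR-221-3p. These 2 miRNAs were 2 of the 3 tested members of their list (camera adjusted p = 0.676). In MC38 Wako, miR-222-3p rested on 3 reads. miR-125b-5p and miR-125a-5p, mammalian relatives of lin-4, were higher by 3.44 (SE 0.87, adjusted p = 0.00523) and 3.37 (SE 0.92, adjusted p = 0.0112). Mir125a lies in an intron of Spaca6 on chromosome 17 (17830812 to 17830879, plus strand), and miR-125b-5p has hairpins on chromosomes 9 and 16. Under Wako, miR-125b-5p was 7.53-fold higher in C26 (exact 95% interval 4.19 to 15.2) and under ExoQuick 15.7-fold (12.1 to 20.6). miR-296-3p differed by 4.44 (SE 1.13, adjusted p = 0.00523), with 7.28 under ExoQuick and 1.61 under Wako, on 5 and 3 reads in the MC38 libraries (Wako ratio 3.06, exact 95% interval 1.01 to 15.2). Mir296 lies on chromosome 2 (174267047 to 174267125, minus strand), in the imprinted Gnas region.

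miR-146a-5p, which is induced by NF-kappa-B and dampens Toll-like receptor signalling, differed most among the named miRNAs that passed (log2 −6.62 for C26 against MC38, SE 1.03, adjusted p = 1.36e-07). It stood at 22983 RPM in MC38 ExoQuick and 33.2 in C26 ExoQuick, a ratio of 693 (exact 95% interval 517 to 951). With Wako it rested on 10 and 6 reads, a ratio of 14.5 (4.78 to 48.6). Its hairpin lies on chromosome 11 (43374397 to 43374461, minus strand), in no annotated gene of that strand. miR-378a-3p, from an intron of the mitochondrial coactivator gene Ppargc1b (chromosome 18, 61397835 to 61397900, minus strand), was higher in MC38 (log2 −2.94, SE 0.82, adjusted p = 0.0159), with ratios of 14.04 under ExoQuick (13.5 to 14.6) and 4.17 under Wako (2.86 to 6.01).

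**Figure D1:**
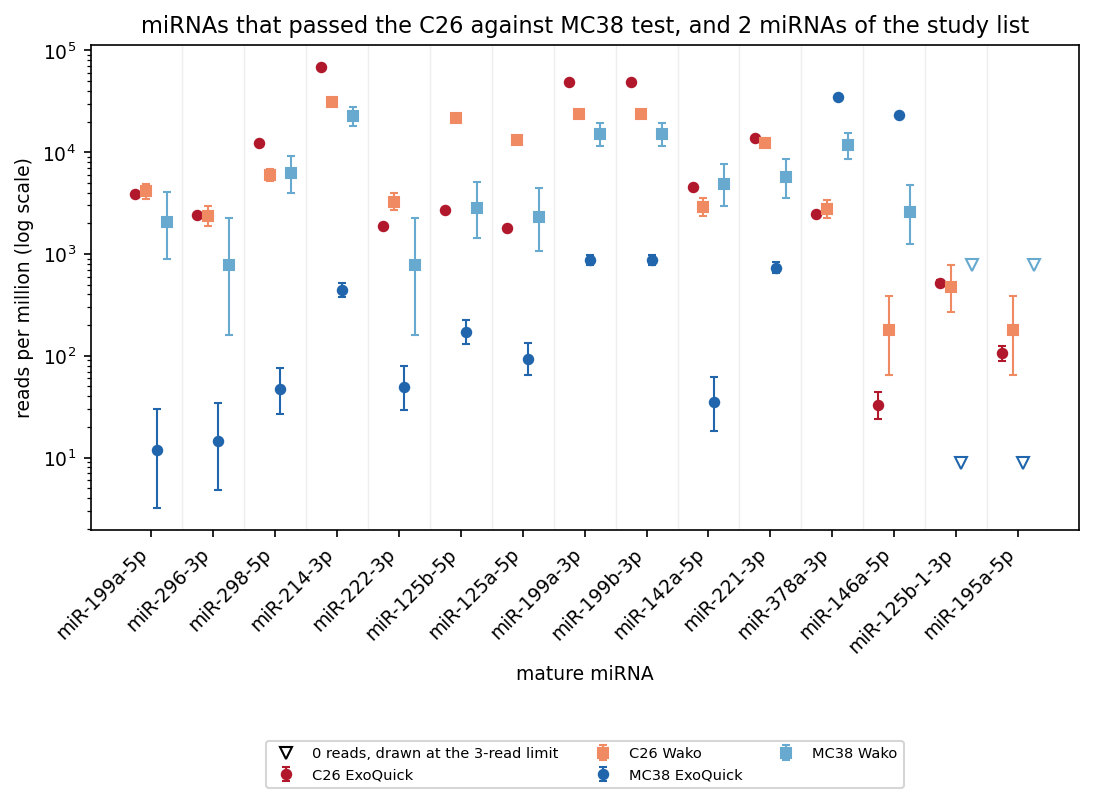
RPM (log axis) of the 13 miRNAs that passed the C26 against MC38 test and of miR-125b-1-3p and miR-195a-5p, in each of the 4 libraries. Points are single libraries, bars are exact 95% counting intervals, and open triangles mark 0 reads at the limit that 3 counts set. The MC38 ExoQuick library is the lowest of the 4 for each of the 11 miRNAs higher in C26, with miR-199a-5p at 11.7 RPM, while MC38 Wako lies near the C26 libraries for several.

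Several miRNAs filled the named places without passing. miR-125b-1-3p stood at 521 and 475 RPM in C26 ExoQuick and C26 Wako and had 0 reads in both MC38 libraries (adjusted p = 0.348), at least 59.2-fold higher under ExoQuick against the 3-count floor of MC38 ExoQuick. miR-669c-5p (at least 37.4-fold, adjusted p = 0.369) and miR-214-5p (at least 29.2-fold, adjusted p = 0.442) had the same form. Under Wako, the C26 values of these 3 were below the floor of MC38 Wako, so that no difference was detectable at that depth. Together with miR-195a-5p, at 105 and 178 RPM in C26 and 0 reads in MC38 (at least 12-fold under ExoQuick), miR-125b-1-3p makes up the pair recalled from a paper on these exosomes. That pair was chosen on these samples, is not independent evidence, and gave 0 of 2 calls, also adjusted over the list alone. edgeR on the recovered reads called miR-125b-1-3p (adjusted p = 0.00217, with 0.000978 to 0.556 over all alternatives). On the MC38 side, miR-211-5p and miR-211-3p, from an intron of the melanocyte gene Trpm1, had 41 and 51 reads in MC38 ExoQuick, 2 and 1 in MC38 Wako and 0 in C26 (adjusted p = 0.477 and 0.549). miR-378d, miR-378a-5p, miR-138-5p, miR-30b-5p, miR-181b-5p and the Clcn5-intron miRNAs miR-188-5p, miR-532-5p and miR-500-3p were the others, with log2 differences from −2.52 to −5.36 and adjusted p from 0.0988 to 0.711.

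Of 20 lists tested for the line difference, 1 passed camera at the preset correlation (adjusted p = 2.66e-05). It stands for the miRNA cluster in an intron of Sfmbt2 on chromosome 2. Its members were taken by name, as every miRNA whose name begins with miR-297, miR-466, miR-467 or miR-669. Membership was not checked by position, so reads from copies elsewhere are not excluded. The cluster did not pass in fry (adjusted p = 0.319) or with an estimated correlation (adjusted p = 0.948), where no list came near passing. In C26 ExoQuick, 47 of its 49 miRNAs had reads, 912 listed reads in all, and in C26 Wako 28 had 73 reads. Both MC38 libraries had 0, so the tested members met the filter through C26 alone. Their direction was thus fixed in advance. Several members share reads, which camera at the preset correlation counts as separate, so its p-value is not support for a difference. Over profiles counted once, the ExoQuick difference was at least 56.5-fold. miR-669c-5p gave 447 of the 675 reads so counted. None of its 16 tested members passed singly, and 13 of them exceeded the MC38 ExoQuick floor in C26 ExoQuick, by a median of at least 1.84-fold. Among miRNAs commonly raised in colorectal tumours, 0 of 4 tested were called, and miR-31-5p and miR-21a-5p were higher in C26 adjusted over the list alone (set adjusted p = 0.676). miR-31-5p was 6.05-fold higher under ExoQuick (exact 95% interval 5.33 to 6.89) and 6.02-fold under Wako (4.02 to 9.43), with an adjusted p of 0.0519 over all tested. Of the list of white blood cell miRNAs, miR-142a-5p was called higher in C26 and miR-146a-5p higher in MC38 (set adjusted p = 0.968). In the miR-99/100, miR-125 and miR-10 list, 2 of 7 were called, and 3 adjusted over the list alone (set adjusted p = 0.809). Of 9 tested miRNAs linked elsewhere to cachexia, muscle wasting or fat loss, miR-378a-3p alone was called, lower in C26. Adjusted over the list alone, 1 was higher and 1 lower (set adjusted p = 0.809).

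The line calls were fragile. None of the 13 passed with median-ratio scaling, quantile normalization, no kit term or no trend (0 calls each in limma, with 33, 53, 25 and 46 miRNAs at unadjusted p under 0.05), and edgeR called 19 (12 higher in C26, 7 in MC38), 4 of them shared. DESeq2 called 21, 11 higher in C26 and 10 higher in MC38. Fits without 1 library could not keep the kit term, and against the 0 calls of 4 libraries without that term they gave 58 without C26 ExoQuick, 43 without C26 Wako, and 0 without MC38 ExoQuick or MC38 Wako (76 and 43 at unadjusted p under 0.05).

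Within each kit, the line differences were larger under ExoQuick for the miRNAs named above that passed. Over the 390 miRNAs, the differences under the 2 kits correlated weakly (Pearson r = 0.309, Spearman rho = 0.308, across miRNAs, which are not independent replicates), and 215 of 351 nonzero pairs had the same sign (61.3%, exact 95% interval 55.9 to 66.4). For miRNAs with 0 reads in MC38 Wako (607 of all 795), the Wako difference could not be negative. Depth thus fixed part of this share in advance, and it does not measure agreement of the kits alone. Among the 76 miRNAs with a mean of at least 1000, r was 0.600 and the SD of the differences was 2.87 under ExoQuick and 1.20 under Wako. At that mean, the highest correlation of log2 values between any 2 libraries was that of C26 Wako with MC38 Wako (r = 0.818), against 0.602 for the C26 libraries and 0.560 for the MC38 libraries. The ExoQuick libraries stood lower, at 0.479, and C26 ExoQuick with MC38 Wako at 0.569, so the libraries did not group by kit throughout. Over all 390 miRNAs the order differed: r was highest between C26 ExoQuick and MC38 ExoQuick (0.758), followed by the C26 libraries (0.719) and the MC38 libraries (0.636), with 0.588 for the Wako pair.

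**Figure D2:**
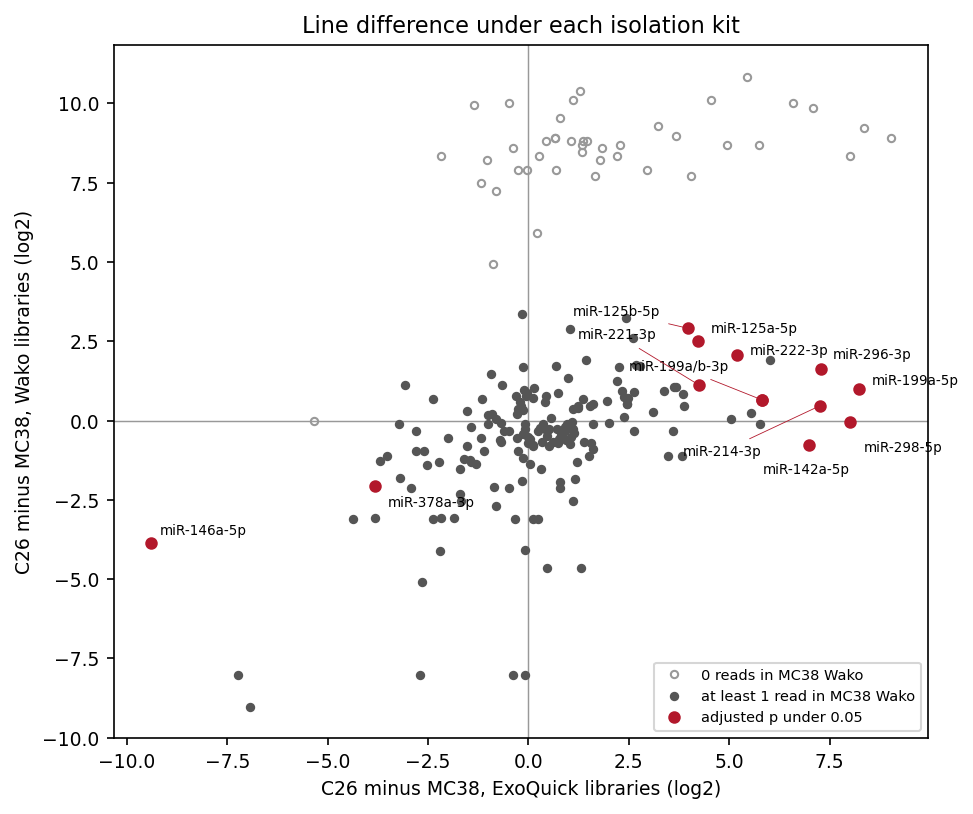
Log2 difference of C26 minus MC38 under ExoQuick (x axis) and under Wako (y axis) for the 217 miRNAs with a mean of at least 100 RPM, each point being 1 miRNA. Red points passed the line test, and open points had 0 reads in MC38 Wako. miR-199a-5p lies at 8.24 under ExoQuick and 0.995 under Wako, and miR-146a-5p at −9.39 and −3.85.

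The second comparison, implied by the 2 isolation kits, asks which miRNAs differ between Wako and ExoQuick with line as a second term. Wako libraries held more of most let-7 family members, of miR-690 and miR-706, and of miR-150-5p, a miRNA of lymphocytes. Of 390 miRNAs, 21 passed, all 21 higher with Wako, and 19 had the same sign in both lines. At unadjusted p under 0.05 there were 53. miR-690, whose hairpin lies in an intron of Fgf12 (chromosome 16, 28599935 to 28600043, minus strand), differed by a log2 of 7.64 (SE 0.89, adjusted p = 5.98e-14). It stood at 80.3 and 235 RPM in C26 and MC38 ExoQuick and at 30601 and 25084 in C26 and MC38 Wako, ratios of 381 (exact 95% interval 312 to 468) and 107 (78.6 to 145). miR-706, from an intron of Wnk1 (chromosome 6, 120034228 to 120034311, minus strand), differed by 5.74 (SE 1.24, adjusted p = 0.000369). miR-150-5p (log2 8.30, SE 2.63, adjusted p = 0.0336), miR-296-5p (4.99, SE 1.62, adjusted p = 0.0399) and miR-351-5p (4.62, SE 1.09, adjusted p = 0.00163) followed, of which miR-150-5p had 3 reads in MC38 Wako and 0 in MC38 ExoQuick, and miR-296-5p had 2 and 1.

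The let-7 family, which restrains growth and rises with differentiation, made up 65799 and 57145 RPM of the C26 and MC38 ExoQuick libraries and 284103 and 302043 of the Wako libraries. Of its 9 members, 6 were called higher with Wako, also adjusted over the list alone: let-7f-5p (log2 4.69, SE 0.84, adjusted p = 8.79e-06), let-7e-5p (4.16), let-7a-5p (4.08), let-7d-5p (3.56), let-7g-5p (3.51) and let-7c-5p (3.35). let-7b-5p (1.15, adjusted p = 0.672), let-7i-5p (0.19, adjusted p = 0.972) and miR-98-5p (−2.50, adjusted p = 0.745) were not. let-7i-5p stood at 9194 and 10915 RPM with ExoQuick and 12911 in C26 Wako. As a set the family did not pass (camera adjusted p = 0.186). Between the lines, 0 of 9 were called, and the family median of 0.14 lay below the 1.85 of all 390 miRNAs. These include miRNAs with 0 reads in MC38 Wako, whose difference depends on the pseudocount. Among the 76 miRNAs with a mean of at least 1000, the median was 0.93 under ExoQuick and 0.28 under Wako. The family medians were −0.25 and 0.47, so the family was not lower than these under Wako. Its fitted median changed sign with the scaling. It stayed below the median of all 390, at −0.23 against 1.31 with median-ratio scaling and −0.27 against −0.05 with quantile normalization.

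**Figure D3:**
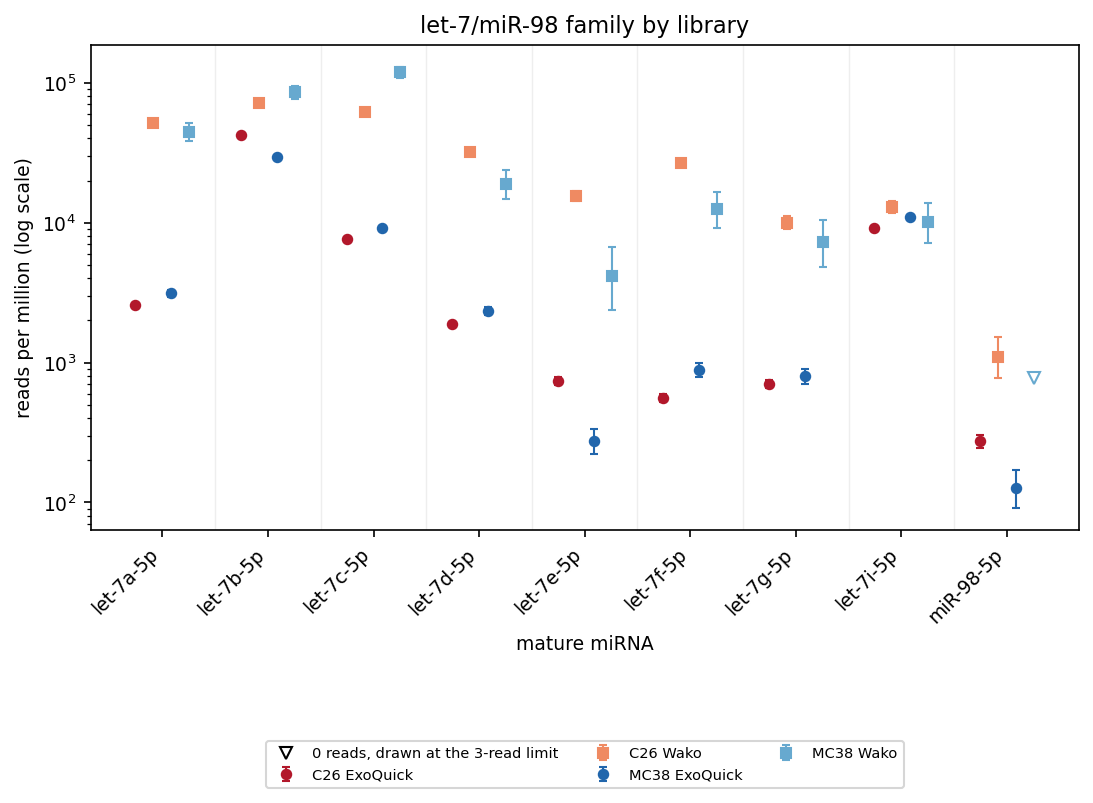
RPM (log axis) of the 9 let-7 family members in each of the 4 libraries, with exact 95% counting intervals. Points are single libraries, and the open triangle marks 0 reads of miR-98-5p in MC38 Wako at the 3-count limit. let-7a-5p lies at 2569 and 3129 RPM with ExoQuick and at 51793 in C26 Wako, and let-7i-5p differs little between the libraries.

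Other members of fixed lists called higher with Wako were miR-125a-5p, miR-125b-5p, miR-31-5p, miR-199a-5p and miR-142a-5p, with log2 differences of 3.76, 3.505, 3.06, 3.72 and 3.21. The last 2 rested on MC38: miR-199a-5p differed by 0.10 in C26 and 7.34 in MC38, and miR-142a-5p by −0.66 in C26 and 7.08 in MC38. miR-23a-5p, miR-342-3p, miR-301a-3p, miR-149-5p and miR-298-5p were also called and are named here after their values were seen. No miRNA passed with a higher level in ExoQuick, and miR-335-5p, miR-101a-3p, miR-33-5p, miR-188-5p, miR-122-5p and miR-130a-3p filled those places with adjusted p from 0.536 to 0.703. In each line the Wako library was the shallower, so kit and depth cannot be separated here. miRNAs higher with ExoQuick can lack reads there and have large SEs (log2 −6.17, SE 4.21 for miR-335-5p), which limits calls in that direction. Called in both comparisons were 5 miRNAs, miR-298-5p, miR-199a-5p, miR-125b-5p, miR-125a-5p and miR-142a-5p. For miR-298-5p, miR-199a-5p and miR-142a-5p, MC38 ExoQuick alone stood apart, at 47.0, 11.7 and 35.2 RPM against 2069 to 12255 in the other libraries. The additive fit divides such a gap between line and kit, so their calls in both comparisons are not separate effects. None of 20 lists passed for the kits in camera, with an estimated correlation or in fry. Their lowest adjusted p was 0.0638 in camera, for miRNAs numbered 3000 or above, and 0.997 with an estimated correlation.

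The kit calls also depended on the scaling. Median-ratio scaling, quantile normalization and no trend gave 0 calls in limma (57, 95 and 31 miRNAs at unadjusted p under 0.05), and TMM scaling gave 4. Without the line term, which fits on 3 libraries could not keep, there were 9 calls with 4 libraries, 11 without MC38 Wako, 0 without C26 ExoQuick or C26 Wako (68 and 100 at unadjusted p under 0.05) and 41 without MC38 ExoQuick, of which 18 were higher with Wako and 23 lower.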

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

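The tests of mixing and counting noise here were chosen after the result was seen, as was the set of 7 miRNAs they use. For miR-298-5p and miR-142a-5p, the line difference had opposite signs under the kits, and the kit difference opposite signs in the lines, and the difference itself was not tested. Under Wako no direction was detectable at this depth, as the exact 95% intervals of the MC38 over C26 ratio held 1 for both, at 1.035 (0.648 to 1.58) for miR-298-5p and 1.69 (0.976 to 2.78) for miR-142a-5p. miR-298-5p, named here after its values were seen, differed between C26 and MC38 by a log2 of 7.997 under ExoQuick and −0.05 under Wako, and between Wako and ExoQuick by −1.03 in C26 and 7.02 in MC38. miR-142a-5p differed between the lines by 6.98 under ExoQuick and −0.76 under Wako, and between the kits by −0.66 in C26 and 7.08 in MC38.

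Both belong to a wider pattern: of the 7 miRNAs at 1000 RPM or more in C26 ExoQuick and under 5% of that in MC38 ExoQuick, all 7 had an exact 95% interval in MC38 Wako above the MC38 ExoQuick value, which argues against counting noise in a library of 3867 reads. Reads of the C26 Wako library as the whole source are argued against, since mixed reads bring every miRNA of their source: of 27 miRNAs outside the set with at least 20 reads expected at the lower 95% limit of the share (61.7%), 4 had fewer reads in MC38 Wako than that (binomial test, adjusted p under 0.05), among them miR-31-5p with 24 against 89.1 expected and miR-125b-5p with 11 against 51.1. For reads of the C26 ExoQuick library, 0 of 11 such miRNAs fell below the limit of 31.8%, and the shares within the set, 36.7% in common, differed beyond counting error (permutation p = 0.00045) but not without miR-142a-5p (permutation p = 0.263). Reads of C26 ExoQuick as the whole source, 1418 reads at the common share or 0.105% of that library, thus cannot be told apart from RNA of MC38 exosomes here, since 1 miRNA decides the test within the set. Smaller parts from either C26 library, and a difference in what each kit recovers from MC38, stay open, untested.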

How the results depend on the processing

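Alternatives added after the data were seen are a mean of at least 1000, identical profiles counted once, a pseudocount of 1 read, edgeR with its own filter, limma-voom, and the scalings of the same-sign share. None of the miRNAs named for passing a test or filling a place reversed under any alternative. The naming rule took only miRNAs with the same sign under both kits or in both lines, so this was partly fixed in advance. It left out miR-298-5p and miR-142a-5p, which were called and differ in sign. Signs of let-7 members moved with the median of all 390 miRNAs: with median-ratio scaling, 6 of 9 were above 0 for the kits instead of 8 and 2 for the lines instead of 7, but the number above that median was 7 and 1 both as deposited and so scaled (7 and 3 with quantile normalization). For the 11 named miRNAs that passed the line test, 121 of 241 refitted values kept the call and 120 lost it, from 6 of 22 for miR-221-3p to 13 of 22 for miR-146a-5p, and for the 6 that passed the kit test 74 of 130 kept it. Of the 275 refitted values of line miRNAs that had not passed, 32 passed. The 13 line calls became 8 with no filter (5 higher in C26, 3 in MC38), 0 with median-ratio scaling, quantile normalization, no trend or a mean of at least 1000 (8 at unadjusted p under 0.05, and fewer miRNAs tested), 8 with robust variances, 21 in DESeq2 (11 higher, 10 lower, 174 adjusted p not given), 37 in edgeR with its own filter and 33 in limma-voom. The 21 kit calls became 14 with no filter, 4 with TMM scaling, 0 with median-ratio scaling, quantile normalization, no trend or a mean of at least 1000 (20 at unadjusted p under 0.05), 7 in edgeR (6 higher with Wako, 1 lower), 15 in DESeq2 (10 and 5), 36 in edgeR with its own filter and 146 in limma-voom. Without the second factor as a block, the line comparison had 0 calls and the kit comparison 9. Leaving out each library in turn, fitted without the second factor and with the lone library assumed to vary like the others, gave 0 to 58 line calls and 0 to 41 kit calls, to be set against that 0 and 9, since 2 choices changed together. The line counts were 58 without C26 ExoQuick, 43 without C26 Wako and 0 without either MC38 library, and 0 of the 13 were shared in any of the 4. The 1 list that passed for the lines became 0 with an estimated correlation, which says little with 1 residual degree of freedom. At a mean of at least 100 only miR-669c-5p of that list was left (mean 231), under the 3 members needed for a test. The list was thus not tested there, and its absence says nothing about it. No other list passed for the lines at that mean, and the 0 lists for the kits became 1. Except where stated, the cause was not tested. The median log2 difference over the same 390 miRNAs moved with scaling, from 1.85 to 1.31 (median-ratio), 1.65 (TMM) and −0.05 (quantile) for the lines, and from 0.44 to −0.61, −0.31 and 0.12 for the kits. The same-sign share of the kits was 61.3% to 63.9% over the pseudocounts (0.5 and 10, which cannot change a sign), filters and 4 other scalings tried, and was not computed under the others. Depth limits the Wako side: 607 of 795 miRNAs had 0 reads in MC38 Wako, where 3 counts are worth 776 RPM. For these the Wako difference could not be negative, so part of the same-sign share was fixed in advance.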

Other observations

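The p53-responsive miR-34a-5p was near level over the libraries (6537, 7628, 6077 and 4655 RPM in C26 ExoQuick, C26 Wako, MC38 ExoQuick and MC38 Wako), while miR-34c-5p was 8.69-fold higher in C26 under ExoQuick (exact 95% interval 7.04 to 10.9) and 1.21-fold under Wako (0.584 to 2.88), and the list gave an adjusted p of 0.809. The miR-29 family, which represses collagen genes, had 0 of 3 calls (adjusted p = 0.809), with miR-29a-3p 4.58-fold higher under ExoQuick (4.28 to 4.92) and 2.36-fold under Wako (1.59 to 3.64). In the miR-17~92 and paralog clusters 0 of 10 were called (adjusted p = 0.599), in the miR-23/27/24 clusters 0 of 5 (0.968), in the miR-15/16 seed family 0 of 6 (0.810), in the miR-30 family 0 of 5 (0.843), in the miR-181 family 0 of 4 (0.678) and in the X-linked cluster of miR-322-5p 0 of 7 (0.843). In the last, miR-351-5p alone was called between the kits.

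Red cell and liver miRNAs that are abundant in serum summed to 848 and 825 RPM in C26 and MC38 ExoQuick and to 1840 and 1552 in C26 and MC38 Wako, with 0 of 5 called (adjusted p = 0.843 for the lines). Of the intestinal and epithelial list, 3 of 5 were analysed here, with 115 reads in C26 ExoQuick, and 2 were tested and not called. Of the miR-200 family and of the embryonic miR-290 and miR-302 clusters, 0 members were analysed here. Muscle miRNAs had 6 reads of miR-206-3p in MC38 ExoQuick and 0 elsewhere. Neuronal miRNAs summed to 4470, 3146, 8775 and 3620 RPM in C26 ExoQuick, C26 Wako, MC38 ExoQuick and MC38 Wako and had 0 of 5 calls, and miR-138-5p was lower in C26 adjusted over the list alone (list adjusted p = 0.809). Of the imprinted Dlk1-Dio3 cluster, 22 of 23 members had reads in C26 ExoQuick and 8 in the shallower MC38 ExoQuick, at sums of 130.5 and 96.9 RPM (177 and 33 reads), with 326.5 and 776 RPM in C26 and MC38 Wako (11 and 3 reads), and 0 of 4 tested were called (adjusted p = 0.809). Entries numbered 3000 or above had 0 of 50 calls in either comparison (adjusted p = 0.678 for the lines). miR-99a-5p had 0 reads in both C26 libraries and stood at 135 RPM in MC38 ExoQuick, at least 61.1-fold higher against the floor of C26 ExoQuick.

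The tests of the let-7 and Sfmbt2 patterns were chosen after the result was seen. The median let-7 difference between Wako and ExoQuick was a log2 of 3.51. Thinning each library to 3953 reads left 3.58 (3.12 to 4.27 over 100 draws). Thinning keeps the levels the same on average, and members lost from an ExoQuick library only widen the difference. A fall was thus hardly possible, and the test cannot decide whether depth plays a part. Removing a linear term in GC content left 3.47 (GC was known for 89.9% of the 217 miRNAs used). That GC content was taken over the side of the hairpin gene that holds the miRNA, not over the mature sequence. Within the family it ran from 38.8% for let-7f-5p to 60.9% for let-7e-5p. As mature sequences were not used, the test cannot decide on the GC content of the miRNAs themselves. Leaving out miR-130a-3p and miR-25-3p, which take a large part of the ExoQuick reads, left 2.92, so their share may account for a part. Under other scalings the median was 2.08 (median-ratio), 2.51 (TMM) and 2.77 (quantile), with 0, 2 and 0 calls. A difference between the kits in the vesicles or RNA they recover was not tested and stays open, as do differences between library preparations, since each combination had 1 library.

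The Sfmbt2-intron cluster, with members taken by name and not by position, was read in both C26 libraries and in neither MC38 library. At its C26 ExoQuick level, 229 listed reads were expected in MC38 ExoQuick (170 over profiles counted once) and 0 were seen, which argues against depth as the cause in that library. In MC38 Wako, 8.40 were expected at the C26 Wako level. A difference between the lines in the transcription of this cluster is a candidate explanation that was not tested, and the comparison rests on 1 library per line and kit.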
